A study of Mus musculus with 4 samples.

How the data were processed

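The series held single-cell RNA libraries of a co-culture of WT and Nfkb1-/- mouse bone marrow cells in Flt3L, 1 expression library and 1 hashtag library for day 3 and the same for day 5, per the labels' protocols made with the 10x Genomics 3' v3 kit and TotalSeq-A hashtag antibodies. The deposited expression files held UMI counts per gene and cell barcode, not normalized, for 8734 barcodes on day 3 and 8515 on day 5 and 31053 genes. They were made with Cell Ranger 3.0 on genome build mm10, per the submitters' processing notes, and the deposited counts name software version 3.1.0, per the file headers. The deposited barcodes each held at least 500 UMIs, from the values. How they were called as cells is not given in the sources used here. The deposited hashtag files held tag counts per hashtag and barcode. Whether the authors counted UMIs or reads there, and with which tool, is not given in the sources used here. A deposited reference table named the genotype and day of each of the 4 hashtags used. Of the 31053 gene symbols, 25162 matched the gene table of assembly GRCm38.p6, the build mm10 is made from, and coordinates are from it.

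Barcodes were given to a genotype by Seurat 5.3.0 (HTODemux, positive quantile 0.99, centred log ratio scaling) over the 2 hashtags of each day, and only singlets were used. Day 3 gave 7583 singlets of 8704 barcodes (87.1%, exact 95% interval 86.4 to 87.8), 241 doublets and 880 barcodes without a call. Day 5 gave 8023 of 8510 (94.3%, 93.8 to 94.8), 251 doublets and 236 without a call. Cells with under 500 genes or over 10% mitochondrial UMIs were left out. To find doublets within a hashtag, Scrublet in Scanpy 1.11.5 was run on all barcodes that passed this filter. It marked 199 barcodes on day 3 and 135 on day 5. Of these, 132 and 70 were hashtag singlets, and they were removed too. Median hashtag counts per barcode differed, at 68 and 29 for the WT and Nfkb1-/- tags of day 3 and at 16 and 162 for those of day 5.

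Cells of both days were clustered together with Scanpy, python-igraph 0.11.9 and NumPy 2.4.6 on counts scaled to 10000 per cell and log-transformed, 2000 variable genes per library without cell cycle, sex-linked and Nfkb1 genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. This gave 23 clusters. A cluster was called after a cell type ("X-like") where at least 3 markers of its list, and more than of any other list, were raised at least 2 times over the other cells and detected in at least 10% of its cells, and where at least 1 marker of that list and no more of another list stood among its 10 genes highest by fold (genes of at least 100 CPM). The markers were fixed beforehand and these thresholds were not. That left 9 clusters without a name, and these are compared by number. Cluster 18 met the rule for macrophages but is also given by number, since genes known from Ly6C-low monocytes stood among its 10 leading genes. The authors' own cell annotation was not used here, so names can differ from theirs.

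Counts were summed per genotype and day. There is 1 pool per genotype and day (3 wells pooled before sorting), so there is no replicate, no test and no p-value. Sums of the deposited counts are given as CPM (scaled to the same total of UMIs in every group) with exact Poisson limits, ratios with exact conditional binomial limits and shares of cells with exact Clopper-Pearson limits, computed with SciPy 1.17.1. The groups held 37931672 to 67069695 UMIs. All of these intervals cover counting error only. A log2 ratio is taken on CPM plus a pseudocount of 1, so it understates the ratio of low genes. "One shared cluster makeup" means CPM computed within each cluster and averaged over the 22 clusters with at least 5 cells in every group, with the same weights in every group (the cluster's mean share over the 4 groups). Of gene IDs that share a symbol, the ID with the most UMIs kept it.

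The rule for named genes, the gene lists, the markers and the alternatives except those called added were fixed before the data were examined. A named gene had at least 50 CPM and 50 UMIs in 1 of the sums compared, and sex-linked, mitochondrial, ribosomal protein genes and Nfkb1 were left out of the ranking. The 12 highest and 12 lowest genes by the smaller of both days' (or, for the day comparison, both genotypes') absolute log2 ratios were named, with the 5 highest and 5 lowest of each day, the 5 highest and lowest within a class, up to 4 members per list with the largest absolute log2 ratios, and always Nfkb1, Sod2, Rela, Relb, Nfkb2, Flt3 and Irf8. For each of 17 lists the median log2 ratio over members with at least 20 CPM was set against 10000 random lists of the same size matched on mean expression in 20 bins. The lists were NF-kB family and regulators, NF-kB targets, reactive oxygen and antioxidant genes, self-renewal and leukaemia-associated genes, myeloid and dendritic lineage transcription factors, antigen presentation, type I interferon response, S phase, G2 and M phase, apoptosis regulators, oxidative phosphorylation, glycolysis, immediate early genes, cholesterol synthesis, chemokine and cytokine receptors, lysosome and phagocytosis, and sex-linked genes. Within classes, sums with at least 100 cells per genotype were compared.

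The counting intervals were tested on simulated data drawn from the real means with 200 genes set 1.5 or 2 times higher or lower. Both groups were drawn as Poisson counts, the model these intervals assume. The test therefore checks their computation and cannot show how they hold under spread between cells or pools. For the genotype ratio, intervals excluded a ratio of 1 for 100% of these genes on both days, and intervals of all 2933 genes of day 3 and 2767 of day 5 held the true value in 95.8% and 95.2%. Alternatives were hashtag calling at quantile 0.999 and by ratio (at least 20 tags and 80% in the top hashtag), no cell filter, a strict filter (1000 genes, 5% mitochondrial UMIs), called doublets kept, Leiden resolutions 0.5 and 2.0, 15 principal components, edgeR 4.0.16 TMM factors, a mean of log values per cell, a pseudocount of 10, list minimums of 5 and 100 CPM, one shared cluster makeup and, within classes, cells thinned to 2000 UMIs. Added after the data were seen were sums without B cell-, neutrophil- and T, NK-like clusters, and a clustering without 187 genes in all, which besides those left out before were 69 genes whose ratio between genotypes exceeded 1.5 times at one shared makeup on either day and the NF-kB family, NF-kB target and antigen presentation lists. It gave 24 clusters. Hashtags not used in a day, tags that matched no hashtag, and barcodes without a call were left out of the comparisons.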

Results

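Bone marrow cells of wild-type mice carrying the CD45.1 allele (the Pep Boy strain) and of Nfkb1-/- mice carrying CD45.2 were mixed at 50% each and grown together with 100 ng/ml Flt3L, the cytokine that drives bone marrow progenitors into dendritic cells. Nfkb1 encodes the NF-kB subunit p50 and its precursor. On day 3 and on day 5, cells of 3 wells were pooled, stained, and sorted into live CD45.1+ (wild-type, WT) and CD45.2+ (Nfkb1-/-) cells negative for CD3, CD19, CD49b, TER119 and Gr-1. Each sorted pool received its own hashtag antibody, the pools of a day were mixed again in equal parts, and 1 single-cell 3' RNA library with 1 hashtag library was made per day. The hashtags gave back 3463 WT and 4120 Nfkb1-/- singlets on day 3 (87.1% of 8704 barcodes) and 3900 WT and 4123 Nfkb1-/- singlets on day 5 (94.3% of 8510 barcodes). After the cell filters, 2936 WT and 3642 Nfkb1-/- cells of day 3 and 3319 WT and 3683 Nfkb1-/- cells of day 5 were compared, holding 37931672, 53813282, 45733555 and 67069695 UMIs in that order. The median cell held 8139, 8629, 10315 and 14943 UMIs. Every group was 1 pool, so no difference below has a replicate check, no test was made and no p-value is given. Intervals are exact 95% intervals and cover counting error only, except those of list medians. The limits of list medians are 95% limits from the ranked log2 ratios of the list's members. They describe the spread among members and hold no counting error.

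The first question set by the study's design was how the loss of p50 bears on RelA and the other NF-kB subunits. Nfkb1 itself (ENSMUSG00000028163, chromosome 3, 135584655 to 135691969 in GRCm38) was counted at 186 CPM (UMIs of a gene scaled to the same total in every group) in WT and 160 in Nfkb1-/- cells on day 3 and at 201 and 163 on day 5, ratios of 0.860 (0.833 to 0.888) and 0.811 (0.789 to 0.834). These counts come from the 3' end of the transcript, which can lie outside the disrupted part of the gene, so they neither support nor oppose the genotype labels. The subunit genes Relb and Nfkb2, which belong to the noncanonical NF-kB arm, were far lower in Nfkb1-/- cells. Relb stood at 34.9 CPM in WT and 10.2 in Nfkb1-/- cells on day 3 (ratio 0.293, 0.265 to 0.324) and at 43.6 and 13.8 on day 5 (0.316, 0.292 to 0.342). Nfkb2 stood at 24.8 and 8.73 CPM on day 3 (0.352, 0.315 to 0.394) and at 24.0 and 9.01 on day 5 (0.376, 0.340 to 0.415). Rela, the gene of RelA, differed little, at ratios of 0.860 (0.806 to 0.917) and 0.836 (0.786 to 0.889). These are transcript counts, and RelA protein and its activity were not measured here. Sod2, the mitochondrial superoxide dismutase, was slightly higher in Nfkb1-/- cells, at 165 against 140 CPM on day 3 (1.18, 1.14 to 1.22) and 134 against 125 on day 5 (1.07, 1.03 to 1.10). Flt3, the receptor of the culture's cytokine, was near equal (1.01 and 0.953). Irf8, a transcription factor of dendritic cell development, was lower (0.662 and 0.784). When both genotypes were given one shared cluster makeup, the log2 ratio of Relb was -0.42 on day 3 and -0.61 on day 5 instead of -1.68 and -1.59, and that of Nfkb2 -0.58 on both days instead of -1.41 and -1.32. Irf8 stood at -0.02 and -0.05 there, Sod2 at 0.13 and -0.07, and Nfkb1 at -0.06 and 0.01. That makeup weights clusters by cells rather than UMIs. It includes mature dendritic cell-like cells, for which Relb is a marker and which held 16 Nfkb1-/- cells on day 3. In the 20 class and day pairs described below, which leave those cells out, the median log2 ratio was -0.94 for Relb and -1.10 for Nfkb2.

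The cells fell into 23 clusters, of which 14 met a naming rule on marker genes fixed before the data were examined, and all of these but cluster 18 are called after a cell type. Dendritic cell classes took smaller shares of the Nfkb1-/- cells, counted over all compared cells, B cell-like and neutrophil-like cells included. Mature dendritic cell-like cells (cluster 3, with the migration receptor gene Ccr7 and Fscn1) made up 3.34% of WT and 0.439% of Nfkb1-/- cells on day 3, a ratio of 0.132 (0.0724 to 0.225), and 5.39% and 1.87% on day 5, a ratio of 0.347 (0.259 to 0.461). Type 1 conventional dendritic cell-like (cDC1-like) cells, with Xcr1 and Batf3, made up 1.499% and 0.522% on day 3 (0.348, 0.192 to 0.609) and 5.03% and 1.52% on day 5 (0.302, 0.219 to 0.411). Type 2 conventional (cDC2-like) cells, with Cd209a and Klrd1, made up 8.004% and 4.59% on day 3 (0.573, 0.467 to 0.702) and 11.1% and 7.25% on day 5 (0.650, 0.554 to 0.763). Plasmacytoid dendritic cell-like (pDC-like) cells, with Siglech and Ly6d, made up 19.2% and 10.4% on day 3 (0.540, 0.473 to 0.617) and 19.6% and 17.5% on day 5 (0.893, 0.7997 to 0.997). Within the pDC-like class the clusters went both ways on day 5, with cluster 5 at 1.49 (1.22 to 1.82), cluster 22 at 1.03, cluster 6 at 0.528 and cluster 21 at 0.630. With hashtags called by the ratio of tags, mature dendritic cell-like cells of day 3 were at 0.213, and with called doublets kept cDC2-like cells were at 0.436 and 0.429. Some genes that define these classes themselves differed between genotypes. In a clustering without such genes, added after the data were seen, the ratios on day 3 and day 5 were 0.148 and 0.352 for mature dendritic cell-like, 0.355 and 0.309 for cDC1-like, 0.616 and 0.846 for cDC2-like, and 0.516 and 0.793 for pDC-like cells.

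**Figure D1:**
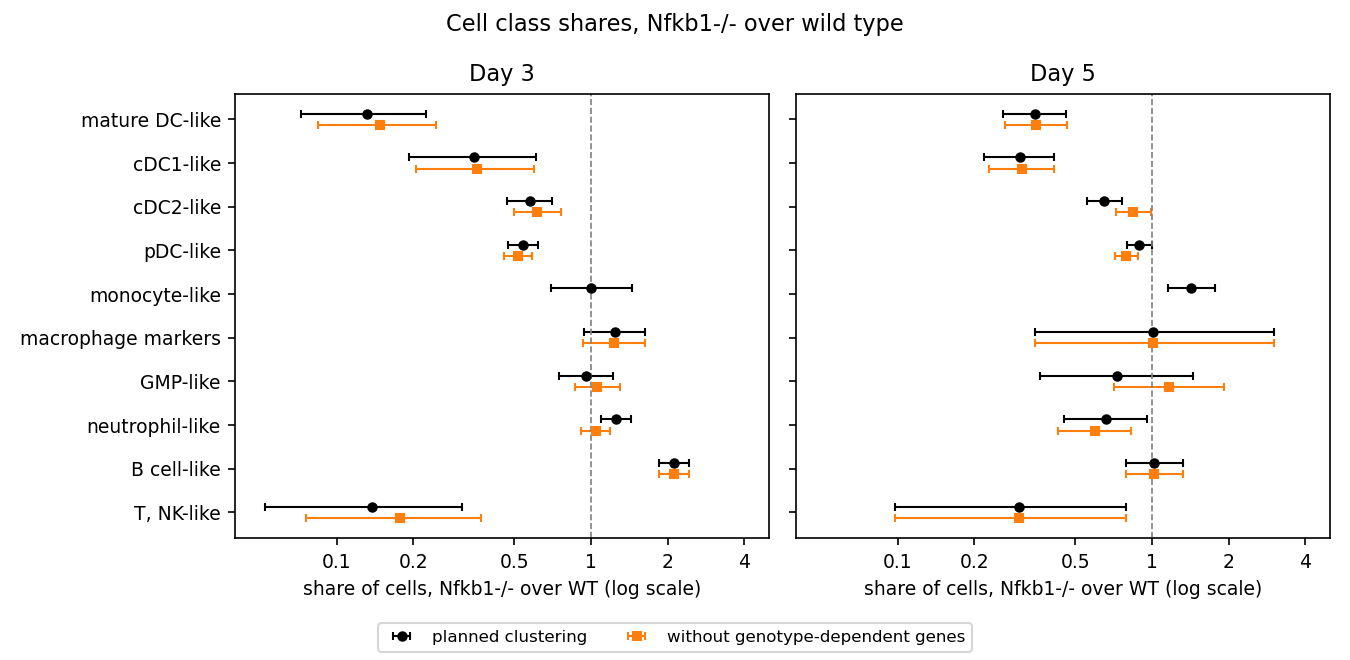
Share of each cell class in Nfkb1-/- cells divided by its share in WT cells (log scale), by day; points are ratios, bars their exact 95% counting intervals, black for the planned clustering and orange for the clustering without genotype-dependent genes, and the black points of the macrophage marker row are cluster 18. Mature dendritic cell-like cells sit lowest among the dendritic cell classes on day 3, at 0.132, and B cell-like cells lie at 2.12 on day 3 and 1.02 on day 5.

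Other lineages went both ways. B cell-like cells, with Cd79a and Ebf1, made up 9.98% of WT and 21.1% of Nfkb1-/- cells on day 3 (2.12, 1.85 to 2.43) and 3.59% and 3.67% on day 5 (1.02, 0.793 to 1.32, and 0.636 with the strict cell filter). Neutrophil-like cells, with Ltf and Camp, made up 11.6% and 14.6% on day 3 (1.25, 1.09 to 1.44) and 2.14% and 1.41% on day 5 (0.660, 0.452 to 0.957). T and NK cell-like cells were 41 of the WT and 7 of the Nfkb1-/- cells on day 3 and 18 and 6 on day 5. The sort removed cells positive for CD19, Gr-1, CD3 and CD49b, so it can set the shares of these 3 classes. All shares are taken over the same total of cells, so it bears on the ratios of the other classes too. The larger B cell-like share of Nfkb1-/- cells on day 3 lowers the other ratios of that day, those of dendritic cell classes among them. The day 3 shares also followed the hashtag calling. Of the 880 day 3 barcodes left without a hashtag, a rule on the ratio of tags assigned 837 to WT, and with that rule the day 3 ratio was 1.39 for B cell-like and 0.911 for neutrophil-like cells. Cluster 19, led by Retnlg and Cxcr2 and kept out of the neutrophil class, held 2.90% of WT and 0.549% of Nfkb1-/- cells on day 3 and 0.723% and 0.299% on day 5. Monocyte-like cells were at 1.94% and 1.949% on day 3 and at 4.34% and 6.19% on day 5 (1.43, 1.15 to 1.77), but at Leiden resolution 2.0 the ratios were 0.045 and 0.2003. Granulocyte-monocyte progenitor-like cells (cluster 9, led by Mgl2, Elane and Mpo) were at ratios of 0.955 and 0.730, and at 0.477 on day 3 with the hashtag ratio rule. On day 5 they were at 1.41 with 15 principal components and at 1.16 without genotype-dependent genes. Cluster 18 met the rule for macrophages, but beside Apoe and Mafb its leading genes held Ear2, Ace and Adgre4, which Ly6C-low monocytes are known to express, so it is given by number. It was at 1.24 and 1.01, and the cells that met that rule were at 0.563 on day 5 with 15 principal components and 0.690 with the strict cell filter. Of the 5 unnamed clusters with a median of 20299 UMIs per cell or more, 4 took larger shares of Nfkb1-/- cells on both days. Cluster 1 (Dntt, Myl10 and histone genes) was at ratios of 1.34 and 1.81, cluster 4 (Dntt, Myl10, Satb1) at 1.46 and 2.70, cluster 10 (Srm, Shmt2, Nolc1) at 1.72 and 1.80, and cluster 15 (Mt1, Hells, Srm) at 1.61 and 1.53. Cluster 2 (histone genes and Esco2), with a median of 21379 UMIs, was at 0.791 (0.630 to 0.993) and 1.15 (0.976 to 1.35). Cluster 11 (Clec4n, Lpl, Adgre1) was lower, at 0.428 and 0.843.

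Summed over all cells, MHC class II genes and NF-kB-linked genes were lower in Nfkb1-/- cells on both days, and genes such as Srm, Nolc1 and Myl10 were higher. The 12 genes lowest on both days held the class II chains H2-Aa, H2-Eb1 and H2-Ab1 and Cd74 and Ciita, their invariant chain and their master transcription factor. Their log2 ratios on day 3 and day 5 were -1.57 and -1.40 for H2-Aa, -1.42 and -1.31 for H2-Eb1, -1.21 and -1.17 for H2-Ab1, -1.25 and -1.07 for Cd74, and -1.28 and -1.25 for Ciita. The cathepsin gene Ctse was lowest of all, at 101 CPM in WT and 5.39 in Nfkb1-/- cells on day 3 and 78.8 and 2.98 on day 5 (log2 ratios of -3.99 and -4.32). The other 6 were Trim12a (-1.26 and -1.25), Lamtor3 (-1.24 and -1.32), Ptms (-1.16 and -1.09), Plbd1 (-0.998 and -1.53), Jaml (-1.09 and -0.93) and Ltb, which encodes lymphotoxin beta (-0.85 and -1.06). The 12 highest were led by Gm47283 (ENSMUSG00000096768), at 4.22 and 90.7 CPM on day 3 and 4.50 and 79.2 on day 5 (4.13 and 3.87). Egfl7 (0.63 and 0.81) and Myl10 (0.60 and 1.05), both among the leading genes of cluster 4, stood beside Rnpep (0.61 and 0.57), Chchd10 (0.78 and 0.44) and Cd81 (0.48 and 0.45). Srm, the spermidine synthase gene (0.47 and 0.49), the nucleolar protein gene Nolc1 (0.47 and 0.48), Ifrd2 (0.42 and 0.45), Gcsh (0.45 and 0.45) and Serpinb1a (0.45 and 0.43) completed the list with Igkc. The Igkc excess (1.19 and 1.62) rested on 1 cell per day with 4135 and 4730 Igkc UMIs, and without the top cell of each group the log2 ratios were 0.23 and -0.53.

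**Figure D2:**
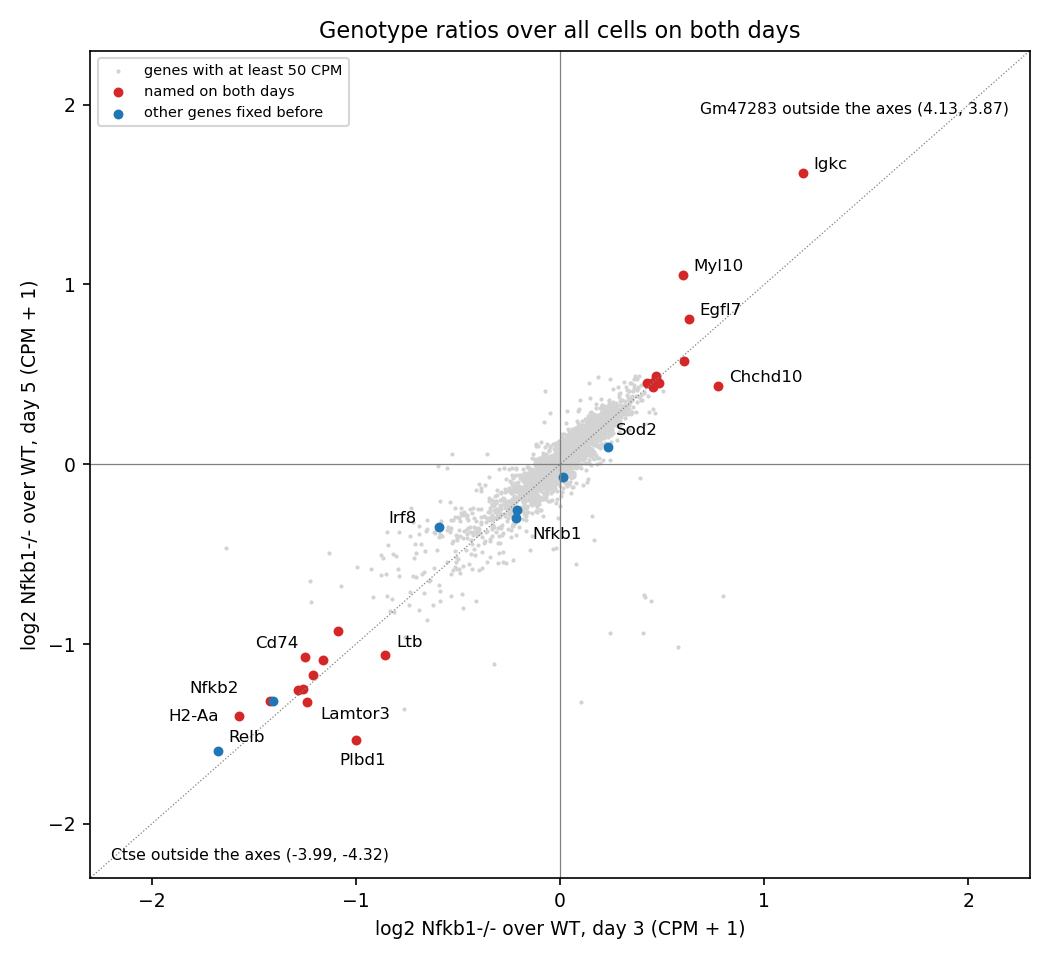
Log2 ratio of Nfkb1-/- over WT cells summed per genotype on day 3 (x axis) and day 5 (y axis), CPM plus a pseudocount of 1; grey points are genes with at least 50 CPM on both days in either genotype, red the 24 genes named on both days and blue the 7 genes always reported. Ctse and Gm47283 lie outside the axes, and Relb and Nfkb2 lie among the lowest genes on both days.

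Genes named for a single day included markers of cell classes that differed on it. On day 3 the B cell genes Vpreb3 (0.92), Ebf1 (0.89) and Iglc1 (0.81) were among the 5 highest (0.34, 0.37 and 0.58 with the hashtag ratio rule), while Ccr9, a homing receptor gene of plasmacytoid dendritic cells (-1.64), and the chemokine gene Ccl5 (-1.63) were among the 5 lowest. On day 5 Ppfia4, which encodes liprin alpha 4, was highest (2.71 CPM in WT and 58.5 in Nfkb1-/- cells, 4.003, and 3.17 on day 3). The basophil protease gene Prss34 (-1.60) and the class II gene H2-DMb2 (-1.50) were among the 5 lowest, with Plbd1. Prss34 stood at 0.90 on day 3, where 2 WT and 8 Nfkb1-/- cells had at least 10 of its UMIs, and at -0.83 there with the hashtag ratio rule and 3.04 with the strict cell filter. That filter also moved Egfl7 to 1.29, Ppfia4 to 3.84 and Igkc to 3.81 on day 3, and Igkc to 3.57 on day 5. With one shared cluster makeup, the log2 ratios on day 3 and day 5 stayed at -4.19 and -4.17 for Ctse, -1.12 and -1.19 for Lamtor3, -0.99 and -0.90 for Trim12a, 3.69 and 3.23 for Gm47283, 4.05 and 4.31 for Ppfia4 and 0.52 and 0.62 for Rnpep. They were nearer 0 for Ltb (-0.44 and -0.85), H2-Aa (-0.37 and -0.45), Ciita (-0.21 and -0.41), H2-Ab1 (-0.09 and -0.27), Cd74 (-0.12 and -0.28), Jaml (-0.07 and -0.15), Ccr9 (-0.18 and -0.02), Egfl7 (0.30 and 0.36), Srm (0.15 and 0.17) and Serpinb1a (0.09 and 0.03). For Ccl5 they were 1.32 and 1.26 and for Igkc -0.20 and -0.0042. Ccl5 was among the 10 leading genes of cluster 3, which held 16 Nfkb1-/- cells on day 3 and 69 on day 5.

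Several of the genes that kept their ratios lie near the genes by which the mice were bred to differ. Ptprc, which encodes CD45, lies on chromosome 1 and Nfkb1 on chromosome 3. Ctse (chromosome 1, 131638314 to 131675507 in GRCm38) and Ppfia4 (chromosome 1, 134296783 to 134344756) lie within 10 Mb of Ptprc, and Lamtor3 (chromosome 3, 137918555 to 137928762) lies within 10 Mb of Nfkb1. Ctse was lower in 20 of the 20 class and day pairs described below with intervals below 1 in 20, Lamtor3 was lower in 20 with such intervals in 18, and Ppfia4 was higher in 20 with intervals above 1 in 16. Rnpep lies within 10 Mb of Ptprc too and was higher in 19 pairs, with intervals above 1 in 19. So does Btg2, named below in B cell-like cells, at 0.83 and 0.82 with one shared cluster makeup.

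**Figure D3:**
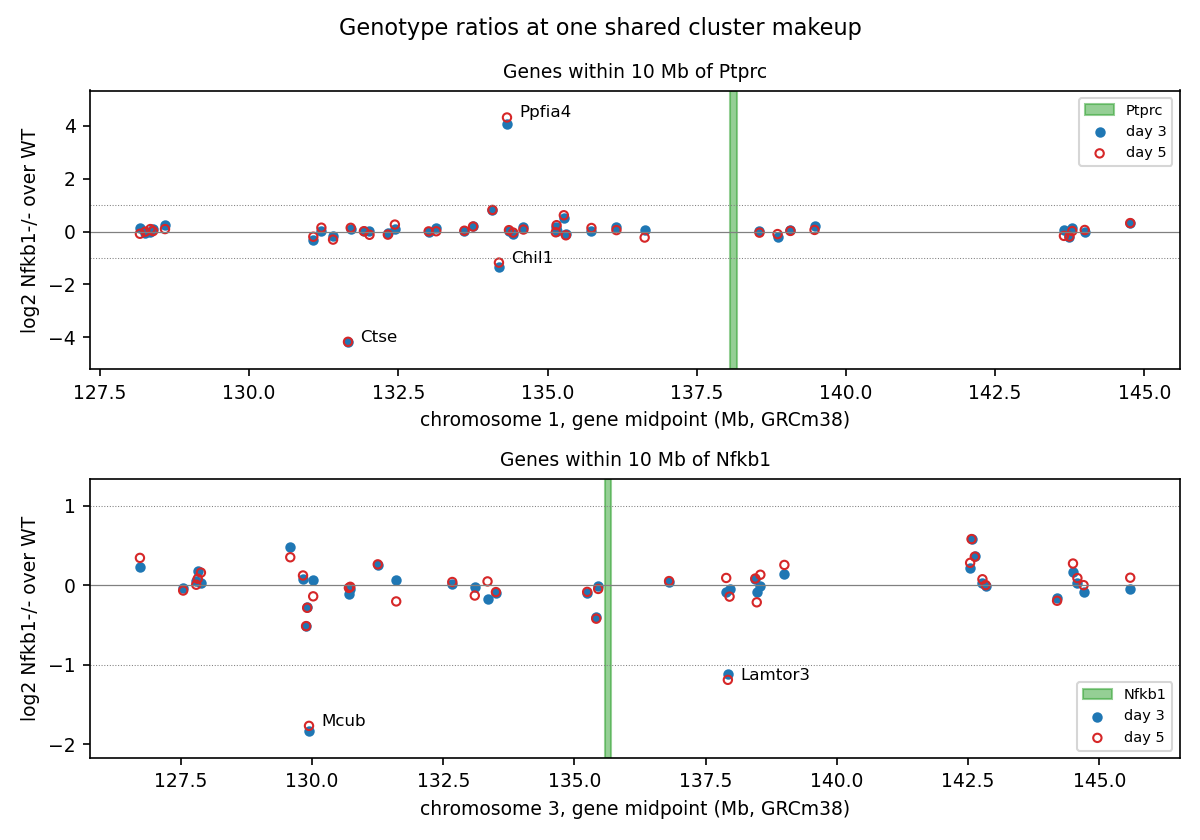
Log2 ratio of Nfkb1-/- over WT cells at one shared cluster makeup (y axis) against position in Mb in GRCm38 (x axis) for measured genes within 10 Mb of Ptprc on chromosome 1 and of Nfkb1 on chromosome 3, on day 3 and day 5. Ctse lies at -4.19 and Ppfia4 at 4.05 on day 3, and Lamtor3 at -1.12.

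The gene lists fixed before the data were examined were read over all cells, where the median of all measured genes was 0.02 on both days. All 13 measured members of the NF-kB family and regulators were lower on both days, with medians of -0.30 and -0.38, below all of 10000 random lists matched on expression. Relb and Nfkb2 led, and the inhibitor gene Nfkbie (-0.82 and -0.96) and the kinase gene Map3k14 (-0.77 and -0.70) came next. Of NF-kB target genes, 15 of 19 on day 3 and 15 of 18 on day 5 were lower (medians -0.40 and -0.44, below all random lists, and -1.01 on day 3 with the strict cell filter), led by Traf1 (-1.92 and -1.45), the survival gene Bcl2a1b (-1.79 and -1.27) and the cytokine gene Il1b (-1.16 and -1.28). Of antigen presentation genes, 15 of 16 and 17 of 17 were lower (-0.72 and -0.61, below all random lists). Of myeloid and dendritic lineage transcription factors, 15 of 16 and 14 of 16 were lower (-0.29 and -0.31, below all random lists), among them Klf4 (-0.88 and -0.61), Spib (-0.74 and -1.21) and Runx2 (-0.72 and -0.32). Type I interferon response genes were lower in 22 of 25 members on day 3 and 19 of 23 on day 5 (-0.40 and -0.12), led by Slfn5 (-0.99 and -0.57) and Phf11b (-0.71 and -0.44). Chemokine and cytokine receptors were lower in 18 of 20 and 18 of 19 members (-0.30 and -0.37), led by Ccr7 (-1.71 and -1.27) and Ccr9. Lysosome and phagocytosis genes were lower in 14 of 15 and 15 of 15 (-0.35 and -0.31), among them Lgals3 (-0.82 and -0.75) and Grn (-0.82 and -0.50).

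In the other direction, 13 of 17 self-renewal and leukaemia-associated genes on day 3 and 9 of 14 on day 5 were higher in Nfkb1-/- cells (medians 0.19 and 0.23), led by the progenitor marker Cd34 (0.74 and 0.75), with Myc (0.47 and 0.39) and Ccnd2 (0.38 and 0.43). All 26 S phase genes were higher on both days (0.13 and 0.22), led by Cdca7 (0.34 and 0.35) and Chaf1b (0.31 and 0.28), as were 24 and 26 of 26 G2 and M phase genes (0.08 and 0.13). Nuclear genes of oxidative phosphorylation were at 0.07 and 0.10, 21 and 23 of 26 higher. The remaining lists lay near 0. Reactive oxygen and antioxidant genes were at -0.009 and 0.02, with Cybb of the phagocyte NADPH oxidase lower (-0.38 and -0.58, and 0.04 on day 3 with the strict cell filter) and Prdx3 higher (0.33 and 0.28). Apoptosis regulators were at -0.08 and -0.02, led by Birc3 (-0.75 and -0.84). Glycolysis was at 0.04 and 0.01, immediate early genes at 0.02 and -0.02 with Junb lower (-0.81 and -0.82), and cholesterol synthesis at -0.08 and 0.006. Of the sex-linked genes, Eif2s3y stood at 61.5 and 40.6 CPM on day 3 and Ddx3y at 41.0 and 41.2. With the hashtag ratio rule, antigen presentation was at -0.48 and the interferon list at -0.22 on day 3. With the strict cell filter, the NF-kB family was at -0.47, S phase genes at 0.40 and G2 and M phase genes at 0.22 on day 3. Of the 16 lists, 6 stayed on their side of 0 on both days under each alternative that gave a value, namely the NF-kB family (no value with list genes of at least 100 CPM), antigen presentation, G2 and M phase, chemokine and cytokine receptors, lysosome and self-renewal lists. Many of these medians were nearer 0 at one shared cluster makeup. There the medians on day 3 and day 5 were -0.14 and -0.23 for the NF-kB family, -0.10 and -0.09 for antigen presentation, -0.05 and -0.04 for chemokine receptors and -0.01 and -0.01 for lysosome genes. They were 0.08 and 0.10 for self-renewal, 0.04 and 0.02 for G2 and M phase and 0.02 and 0.03 for oxidative phosphorylation genes. On day 3 they were 0.12 for NF-kB targets, 0.03 for lineage transcription factors, 0.09 for interferon response genes and -0.003 for S phase genes. On day 5 -0.03 for NF-kB targets, -0.07 for lineage transcription factors, 0.16 for interferon response genes and 0.02 for S phase genes. Traf1 (0.04), Ccr7 (0.28), Phf11b (0.01) and Lgals3 (0.03) were above 0 there on day 3. Ccr7 was among the leading genes of cluster 3, which held 16 Nfkb1-/- cells on that day.

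Whether these ratios also stood inside cell types was asked in the classes and clusters with at least 100 cells of each genotype, 20 class and day pairs in all. Mature dendritic cell-like cells, for which Relb is a marker, and cDC1-like cells are not among them. They held 16 and 69, and 19 and 56, Nfkb1-/- cells on day 3 and day 5. Nfkb1 was lower in 10 pairs and higher in 10. Nfkb2 was lower in Nfkb1-/- cells in 20 of 20 (median log2 ratio -1.10, intervals below a ratio of 1 in 18) and Relb in 19 of 20 (-0.94, 17). Both genes were low in some pairs. In WT and Nfkb1-/- cells of cluster 4 on day 3, Relb was at 14.4 and 9.29 CPM and Nfkb2 at 10.1 and 4.64. Thinned to 2000 UMIs per cell, Relb turned to 0.31 in the granulocyte-monocyte progenitor-like cells of day 3 and to 0.86 in cluster 4 of day 3. Rela was lower in 17 pairs with intervals below 1 in 3, and Sod2 was higher in 15 with intervals above 1 in 5 (median 0.11). The MHC class I gene H2-K1 was lower in 20 of 20 (-0.71, 20), Cd74 in 20 (-0.48, 18), H2-Aa in 19 (-0.65, 14) and Irf8 in 18 (-0.22, 14). The antigen presentation list had a median below 0 in all 20 pairs and below the 5th percentile of matched random lists in 19. The NF-kB family list lay below 0 in 19 and below that percentile in 11. The lineage transcription factor list did so in 17 and 14, and NF-kB targets in 12 and 9, with NF-kB targets above 0 in the other 8 and above the 95th percentile in 2. Other lists shifted over all cells went both ways here. S phase genes were lower in 10 pairs and higher in 10, G2 and M phase genes in 8 and 12, and interferon response genes in 11 and 9. Chemokine receptors and lysosome genes were each lower in 14 and higher in 6. Self-renewal genes were higher in 16 and oxidative phosphorylation genes in 19.

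**Figure D4:**
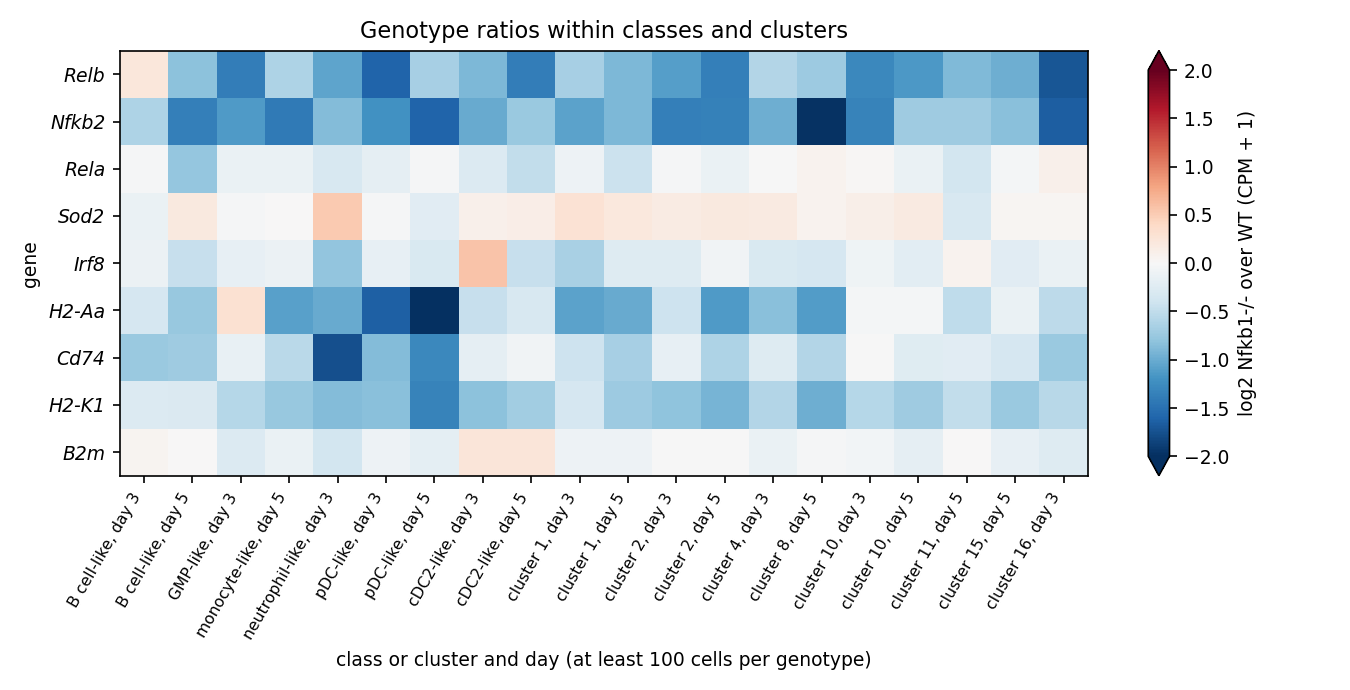
Log2 ratio of Nfkb1-/- over WT cells (CPM plus a pseudocount of 1) for 9 genes in each class or cluster and day with at least 100 cells per genotype; blue is lower and red higher in Nfkb1-/- cells, and the colour scale ends at 2 in either direction. Nfkb2, Cd74 and H2-K1 are lower in all 20 columns and Relb in 19.

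Single classes held further genes. In pDC-like cells, whose largest cluster was cluster 6 for WT (215 of 564 cells) and cluster 21 for Nfkb1-/- (125 of 378) on day 3 and cluster 21 (336 of 651) and cluster 5 (267 of 645) on day 5, H2-Aa was at log2 ratios of -1.63 and -2.33 and Khk, the fructokinase gene, at -1.57 and -1.35. Higher there were Il12a, a cytokine subunit gene (1.55 and 1.42), and Marcksl1 (1.04 and 1.07). In cDC2-like cells Ly6a, the gene of the progenitor and activation antigen Sca-1 (1.39 and 1.47), the cytokine gene Il18 (1.51 and 1.75) and the mitotic gene Kif23 (1.60 and 1.36) were higher. Fabp5, a fatty acid-binding protein gene, was lower (-1.74 and -1.69). In B cell-like cells Cd52 (-1.33 and -1.16), Cd74 (-0.74 and -0.72) and Mcl1, a survival gene (-0.37 and -0.51), were lower, and Btg2 (0.81 and 0.93) and the kinase gene Pim1 (0.59 and 0.54) higher. Btg2 lies within 10 Mb of Ptprc. In the unnamed clusters 1 and 2, Ide, the insulin-degrading enzyme gene, was lower in both (-0.81 and -0.79, and -0.89 and -0.95) and Ly6a higher (0.51 and 0.56, and 0.64 and 0.54). In cluster 10, Ms4a3, a granulocyte-monocyte progenitor gene, was lower (-1.40 and -1.16).

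The last comparison set day 5 against day 3 within each genotype, and as each day was 1 library, day and library cannot be told apart. Glycolysis genes were higher on day 5 in both genotypes, and neutrophil marker genes were lower. The median log2 ratio of all measured genes was -0.08 in both genotypes (0.04 and 0.05 with TMM scaling), and day values are read relative to it. Nfkb1 was at 0.10 in WT and 0.02 in Nfkb1-/- cells, and in WT cells at -0.18 with the strict cell filter and -0.09 with one shared cluster makeup. In WT and Nfkb1-/- cells in that order, the highest genes were Ankrd37 (2.05 and 2.49), the mitophagy gene Bnip3 (1.99 and 2.19), the lactate transporter gene Slc16a3 (1.96 and 2.26) and Ifitm1 (1.67 and 1.70). The glycolysis enzyme genes Pgk1 (1.16 and 1.11), Tpi1 (1.08 and 1.02), Eno1 (1.01 and 1.02) and Aldoa (1.03 and 1.00) followed with Mt1 (1.27 and 1.08), Pid1 (1.14 and 1.16), Cysltr1 (1.11 and 1.35) and Cd7 (1.01 and 1.20). With the strict cell filter Pid1 was at 0.34 and 0.20, Cysltr1 at 0.33 in WT, Mt1 at 2.00 in WT and Slc16a3 at 1.45 in Nfkb1-/- cells. Over the glycolysis list, 14 of 16 members in WT and 14 of 15 in Nfkb1-/- cells were higher, with medians of 0.74 and 0.75, above all of 10000 random lists.

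The lowest genes on day 5 were Ltf (-3.10 and -4.28), Camp (-2.87 and -4.46), Wfdc21 (-2.76 and -3.92), Lcn2 (-2.73 and -4.07), Ngp (-2.65 and -3.85), Chil3 (-2.49 and -4.02), S100a8 (-2.47 and -3.60), S100a9 (-2.40 and -3.56), Mpo (-2.39 and -2.96) and Mgst1 (-2.25 and -2.57), most of them granule or antimicrobial genes of neutrophils and their precursors. With the strict cell filter Ltf was at -4.28 and -5.58, S100a9 at -3.66 and -4.88 and Mpo at -0.64 and -0.95. The neutrophil-like share stood beside them, at 11.6% and 14.6% on day 3 and 2.14% and 1.41% on day 5, and with one shared cluster makeup S100a8 was at 0.23 and 0.10, S100a9 at 0.30 and 0.17 and Chil3 at 0.25 and -0.34. The other members of the 12, Gm42418 and Lars2, which are known to collect ribosomal RNA reads, were lower on day 5 with the shared makeup too (-2.88 and -2.90, and -2.78 and -2.87, against -2.98 and -3.13, and -2.80 and -2.80, over all cells). Relative to the all-gene median, the antigen presentation list was higher (0.47 and 0.41), led by Cd74 (0.78 and 0.96) and Ctss (0.74 and 0.95). That order did not hold in every setting, as the list was at -0.33 and -0.25 with the strict cell filter and at -0.12 and -0.18 with the shared makeup. With the strict cell filter Cd74 was at -0.09 in WT cells, and with the shared makeup at -0.02 in Nfkb1-/- cells. Self-renewal genes were lower (-0.27 and -0.33), led by Cd34 (-1.38 and -1.37) and Myb (-1.03 and -1.09), and so were S phase genes (-0.22 and -0.17). The strict cell filter put the self-renewal list at -0.0049 and 0.019 (0.0064 and 0.024 as a mean log value per cell), Cd34 at -0.76 and Myb at -0.18 in WT cells, and S phase genes at 0.28 and 0.08. G2 and M phase genes were higher (0.10 and 0.18), led by Ube2c (0.43 and 0.54). Of the remaining lists, in the same order, oxidative phosphorylation was at 0.14 and 0.17, cholesterol synthesis at 0.10 and 0.18, chemokine receptors at 0.13 and 0.07, lysosome genes at 0.10 and 0.23, and interferon response genes at -0.11 and 0.14 (-0.43 and -0.39 with the shared makeup). With the strict cell filter, chemokine receptors were at -0.22 and -0.06 and lysosome genes at -0.03 and 0.14. The NF-kB family was at 0.03 and -0.01, its targets at 0.12 and 0.06, apoptosis regulators at 0.02 and 0.08, reactive oxygen genes at -0.06 and -0.09, and lineage transcription factors and immediate early genes between -0.10 and -0.09. The NF-kB family was at -0.36 and -0.04 with the strict cell filter and at -0.06 and -0.17 with the shared makeup, and its targets at -0.40 and -0.25 and at -0.06 and -0.18. Of the 16 lists, 4 stayed on their side of 0 in both genotypes under each alternative that gave a value, namely glycolysis, G2 and M phase, oxidative phosphorylation and cholesterol synthesis (no value with list genes of at least 100 CPM).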

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

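No explanation was tested for the values in this part. Each genotype difference given here lay on opposite sides of 0 (or of a share ratio of 1) on day 3 and day 5, with both counting intervals leaving out no difference. The difference between the days itself was not tested, since each day was 1 library. With the hashtag ratio rule, 3 of the 14 genes (Camp, Chil3 and Iglc1) still lay on opposite sides of 0 on the days, and at one shared cluster makeup 7 of 14 did, so most of these values depend on the hashtag calling.

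Neutrophil marker genes were higher in Nfkb1-/- cells on day 3 and lower on day 5. The log2 ratio of day 5 minus that of day 3 was -1.18 for Ltf, -1.59 for Camp, -1.16 for Wfdc21, -1.34 for Lcn2, -1.20 for Ngp, -1.53 for Chil3, -1.14 for S100a8, -1.15 for S100a9 and -0.56 for Mpo. The neutrophil-like share ratio of day 5 divided by that of day 3 was 0.527. With the hashtag ratio rule the day 3 values were -0.16 for Ltf, -0.19 for Wfdc21, -0.090 for Lcn2, -0.14 for Ngp, -0.095 for S100a8, -0.065 for S100a9 and -1.04 for Mpo, and the neutrophil-like share ratio was 0.911. Without the B cell-, neutrophil- and T, NK-like clusters, the day 3 values were -0.23 for Ltf, -0.064 for Camp, -0.83 for Wfdc21, -0.87 for Lcn2, -0.056 for Ngp, -0.61 for Chil3, -0.96 for S100a8 and -1.04 for S100a9. With the strict cell filter Mpo was at 0.95 on day 5. B cell genes were also higher on day 3 and lower on day 5, with differences of -1.08 for Vpreb3, -1.06 for Ebf1 and -1.19 for Iglc1, as were the basophil protease gene Prss34 (-2.50) and Cd63 (-1.49). With the hashtag ratio rule Prss34 was at -0.83 and Cd63 at -0.64 on day 3, and Vpreb3 at 0.062 and Ebf1 at 0.096 on day 5. The share ratio of cluster 5, 1 of 4 pDC-like clusters, was 2.17 times higher on day 5 than on day 3.

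Tags of hashtags that marked no cells of a day were also counted. The day 3 library held 538 tags of hashtag 3, 18 of hashtag 4 and 75 of hashtag 5, and 188854 tags that matched no hashtag. The day 5 library held 646 tags of hashtag 1, 3100 of hashtag 2, 4737 of hashtag 4 and 378121 unmatched tags. Hashtag 4 was assigned to no cells in either library.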

How the results depend on the processing

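The alternative chosen after the data were seen was the clustering without genotype-dependent genes, with the sums that leave out B cell-, neutrophil- and T, NK-like clusters. No paired analysis was made: a fit over both days with genotype and day as terms leaves 1 residual degree of freedom and was not run. Lists of genes of at least 100 CPM gave no value for the NF-kB family and cholesterol synthesis. Of 144 class share ratios under alternatives, 132 lay on the same side of 1 as reported. Of 696 list medians 616, of 314 values within classes 292 and of 1854 gene values 1786 lay on the same side of 0. The 206 gene values with a pseudocount of 10 could not change side, so the gene count overstates the agreement. Of the gene values, 736 moved out of the reported value's counting interval. A further 57 turned although that interval left out no difference. At one shared cluster makeup 14 of 206 gene values stayed within it. The 206 gene values as a mean log value per cell lie on another scale and were not counted as moved. By day, antigen presentation lay below 0 with the strict filter (-0.33 and -0.25) and one shared makeup (-0.12 and -0.18). Where no construction is named, the cause was not tested. Depth limits B cell-like cells most, of which 24 of 119 WT and 23 of 135 Nfkb1-/- cells of day 5 held 2000 UMIs.

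Singlets made up 77.1% of barcodes on day 3 and 88.4% on day 5 at the stricter hashtag quantile, and 94.2% and 96.6% by the hashtag ratio rule. By that rule the day 3 share ratio was 1.39 for B cell-like, 0.911 for neutrophil-like and 0.760 for pDC-like cells, Prss34 was at -0.83, Cd63 at -0.64, Ltf at -0.16, Wfdc21 at -0.19, Lcn2 at -0.090, Ngp at -0.14, S100a8 at -0.095, S100a9 at -0.065 and Mpo at -1.04 on day 3, and Ebf1 at 0.10 and Vpreb3 at 0.062 on day 5. Neutrophil-like cells of day 3 were at 1.04 at resolution 0.5, 1.05 with 15 principal components and 1.04 without genotype-dependent genes, where day 5 ratios were 0.793 for pDC-like and 0.846 for cDC2-like cells. Monocyte-like cells of day 5 were at 0.2003 at resolution 2.0. Without a cell filter pDC-like cells of day 3 were at 0.679. With the strict filter they were at 0.626, B cell-like cells of day 5 at 0.636, Cybb on day 3 at 0.042, Mpo on day 5 at 0.95, and by day Nfkb1 at -0.18 and Cd74 at -0.090 in WT and S phase at 0.28 and 0.075. With called doublets kept, cDC2-like ratios were 0.436 and 0.429. Without the B cell-, neutrophil- and T, NK-like clusters Ebf1 was at 0.16 on day 5, and on day 3 Ltf at -0.23, Camp at -0.064, Wfdc21 at -0.83, Lcn2 at -0.87, Ngp at -0.056, Chil3 at -0.61, S100a8 at -0.96 and S100a9 at -1.04.

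One shared cluster makeup removes differences in class shares by construction, and it weights clusters by cells rather than UMIs. There the NF-kB family was at -0.14 and -0.23, antigen presentation at -0.10 and -0.091, and on day 3 NF-kB targets at 0.12, lineage transcription factors at 0.025, interferon response at 0.086, S phase at -0.0029 and cholesterol synthesis at 0.025, with interferon response at 0.16 on day 5. On day 3 Ccr7 was at 0.28, Igkc at -0.20, Ccl5 at 1.32, Traf1 at 0.035, Phf11b at 0.012, Lgals3 at 0.034, Ltf at -0.11 and Wfdc21 at -0.047. On day 5 Nfkb1 was at 0.015, Sod2 at -0.072, Ccr7 at 0.063, Ebf1 at 0.17, Igkc at -0.0042, Vpreb3 at 0.24, Iglc1 at 0.070, Ccl5 at 1.26, Map3k14 at 0.0033, Phf11b at 0.15, S100a8 at 0.014, S100a9 at 0.017 and Prdx3 at -0.018. By day, Nfkb1 (-0.088), Chil3 (0.25), S100a8 (0.23) and S100a9 (0.30) turned in WT, and S100a8 (0.10), S100a9 (0.17) and Cd74 (-0.024) in Nfkb1-/- cells. As a mean log value per cell, oxidative phosphorylation was at -0.017 on day 3, interferon response at 0.022, Ebf1 at 0.010, Igkc at -0.041, Vpreb3 at 0.017, Iglc1 at 0.0020 and Mpo at 0.0055 on day 5, and S phase by day at 0.0032 and 0.078. In cells thinned to 2000 UMIs, Relb of day 3 was at 0.31 in granulocyte-monocyte progenitor-like cells and 0.86 in cluster 4.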

Other observations

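The tests in this part, and the genes first named in it, were chosen after the result was seen, except the test of the genes defining the mature dendritic cell-like class. In cDC2-like cells, where the antigen presentation median was -0.25 on day 3 and -0.07 on day 5, other gene groups were higher. The type I interferon response list was at a median log2 ratio of 0.42 on day 3 (24 of 26 members higher) and 0.54 on day 5 (26 of 26). S phase genes were at 0.64 (24 of 24) and 0.36 (23 of 23), and G2 and M phase genes at 0.33 (21 of 22) and 0.90 (21 of 21). NF-kB target genes were lower there (-0.53 and -0.43). The clustering without genotype-dependent genes left out 7 of the 10 leading genes of its cDC2-like class. In it, 259 of the 370 WT and 199 of the 267 Nfkb1-/- cells of day 5 kept that class. Whether these values follow which cells fell into the class was not tested. Neutrophil-like cells of day 3 had a lower interferon list (-0.43) and higher S phase genes (1.14), and 19 WT but 101 Nfkb1-/- cells of that day sat in cluster 12, the neutrophil-like cluster led by Fcnb and Chil3.

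The Igkc excess came with 1 Nfkb1-/- cell per day in cluster 10. The day 3 cell held 4135 Igkc, 586 Jchain and 836 Igha UMIs of 10049, and the day 5 cell 4730 Igkc, 454 Jchain and 1110 Ighm UMIs of 11684, genes that plasma cells are known to express. On chromosome 7 the neighbours Trim34a (-1.0007 and -1.01 at one shared cluster makeup), Trim5 (-1.03 and -1.30) and Trim12a (-0.99 and -0.90) were lower together. They belong to a family of near-identical copies whose reads can be split between members, so the single values are uncertain. Casp4 on chromosome 9 was lower too (-1.06 and -1.11).

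Of 11 genes with known coordinates and ratios of at least 2 times the same way on both days at one shared cluster makeup (Gm47283, without coordinates, was left out), 5 lay within 10 Mb of Ptprc (Ctse, Chil1, Ppfia4) or Nfkb1 (Mcub, Lamtor3), 45.5% (16.7 to 76.6) against 1.43% of 5583 measured genes with coordinates, 31.72 times (11.7 to 53.5). The limits treat the 11 genes as independent. Ctse, Chil1 and Ppfia4 lie close together on chromosome 1, and Trim34a and Trim5 are neighbours on chromosome 7, so the limits are too narrow. A different cell makeup was tested on the 5 genes near either allele with ratios of at least 2 times over all cells, whose median absolute log2 ratio at the shared makeup was 0.668 of its size on day 3 and 0.6178 on day 5. The genes moved both ways there, with Ppfia4 farther from 0 and Mcub and Lamtor3 nearer to it on both days, and 5 of 5 kept ratios of at least 2 times, a limit set after their values were seen. Makeup as the whole cause is argued against for 3 of them inside the 20 class and day pairs, where intervals lay below 1 in 20 for Ctse and 18 for Lamtor3 and above 1 in 16 for Ppfia4. The values are consistent with segments of the donor strains carried along with the Ptprc and Nfkb1 alleles, a hypothesis that needs genotypes to test, and whether loss of p50 itself acts on these genes stays open.

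Mature dendritic cell-like cells took smaller shares of Nfkb1-/- cells under all 8 alternatives run for them, at ratios of 0.132 to 0.213 on day 3 and 0.352 to 0.414 on day 5. The larger of both days' share ratios was 0.3825 with the hashtag ratio rule, 0.366 without a cell filter and 0.3516 in the clustering without genotype-dependent genes, with upper counting limits under 1 on both days. Those settings argue against hashtag calling and the cell filter as the whole cause. For the defining genes, they argue only against those left out, 5 of the class's 10 leading genes in that clustering. Its clusters were still named by the same markers, Relb among them, so the other defining genes stay open as a cause. A lower rate of maturation or survival may be the cause, but neither was tested.

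Antigen presentation genes were lower over all cells, with medians of -0.72 and -0.61, and less so at one shared makeup. There the median was -0.10 (limits over list members -0.21 to 0.006) on day 3 and -0.09 (-0.29 to -0.05) on day 5. These genes were not left out of the planned clustering, and H2-Aa, Ciita and Cd74 were among the leading genes of cluster 0 (cDC2-like). A genotype effect on them could move cells between clusters, so the shrinkage cannot be credited to makeup alone. Makeup as the whole cause is argued against by the classes and clusters, where the list lay below the 5th percentile of matched random lists in 19 of 20 pairs. It did so in 22 of 23 pairs of a single cluster and day with at least 100 cells per genotype (the exception being cluster 10 of day 3). Both counts rest largely on the same sums, since only the neutrophil-like and pDC-like classes pool clusters. Members of the list can vary together, which random lists do not copy, so the percentiles are a description. The pDC-like class pools 4 clusters, and weighted alike these were at -0.43 (-0.74 to 0.02) and -0.35 (-0.86 to -0.15), with cluster 22 of day 3 at -0.08 (-0.49 to 0.05) and 2 of the 4 clusters with intervals below -0.1 on both days. Strain variants in the MHC region of chromosome 17 stay open beside an effect of p50 loss, as neither limit of their test was met. The list members on other chromosomes, 3 to 5 per cluster, had a median below 0 in 22 of 23 such pairs, more than the limit set for such variants. Their median was under -0.1 in 17 of 23, short of the 3 in 4 set for arguing against them. Cd74 (chromosome 18) was lower in 23 of 23 pairs, Ciita (chromosome 16) in 12 of 12 and Ctss (chromosome 3) in 17 of 23. B2m (chromosome 2) was lower in 16 of 23 and Cd86 (chromosome 16) in 1 of 5.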
